A study of Pseudomonas aeruginosa PAO1 with 6 samples.

How the data were processed

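Messenger RNA was sequenced from Pseudomonas aeruginosa PAO1, a reference laboratory strain of an opportunistic bacterial pathogen. The series holds 6 libraries, 3 labelled control and 3 labelled DATS, all taken after 5 h of shaking culture in LB, a rich broth. The labels do not spell out DATS. Per the labels' protocols, diallyl sulfide, an organosulfur compound found in garlic, and diallyl ether were added at 0 or 0.625 µl/mL, and which of these names the DATS cultures correspond to is not stated. RNA was extracted with Trizol and made into libraries with a TruSeq kit and a strand-specific step, per the labels' protocols. The labels call the samples triplicates without saying that each came from its own culture, so the p-values measure the spread between these libraries.

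The authors deposited a table of 5572 protein-coding genes with a count and an FPKM column for each library. Per the submitters' processing notes, Bowtie2 2.0.6 and TopHat2 2.0.9 were used. The counting tool, its strand setting, the genome build and the annotation are not given in the sources used here. The deposited counts are estimated counts: they were whole numbers in 98.9% of genes and held decimals in 59 genes, which include near-identical copies such as the 2 phenazine operons. Values of these 59 genes depend on how the authors' counting divided shared reads and are uncertain. Because the strand setting is not given, reads from overlapping or antisense genes could not be separated here. The deposited FPKM columns hold the authors' values scaled by gene length and by the library's total count. The gene length that they imply was computed for 4624 genes with at least 50 counts in a library, and it lay within 5 bases of the RefSeq length for 4623 of them. A further table of the authors' group means was not used. Per the file headers, the treated libraries are called DTS, and they were matched to the DATS samples by this name and their number. All 5572 locus tags were found in the RefSeq gene table of the PAO1 assembly, which served to check names and lengths. No coordinates are given, because the authors' build is not given in the sources used here.

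Total counts per library were 4525236, 4073536 and 4624041 in control replicates 1, 2 and 3 and 6912818, 5140123 and 5436335 in DATS replicates 1, 2 and 3. The median gene had 128 to 174 counts. A count of 0 allows up to 3 counts, which is 0.434 to 0.736 CPM depending on the library. Intervals and floors cover counting error only. No library was a copy of another of its group, with a chi-square per degree of freedom of 12.1 to 147 between them, which does not show that they came from separate cultures. Each library was used as a replicate because the labels number it as one.

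Counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr, which left 5280 and removed 292. Libraries were scaled by TMM, with factors of 0.903 to 1.10. The robust quasi-likelihood test compared the 3 DATS with the 3 control libraries, with no covariate, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Fold changes are DATS over control on the log2 scale. The standard error (SE) of a fold change was taken from the test statistic. CPM is used for counts scaled to a common library size with the TMM factors. Before the data were examined, 20 gene lists were fixed by locus tag, and each was tested with camera of limma 3.58.1 on log2 CPM, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 20 lists. The same test was repeated with a correlation estimated for each list, and with fry.

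The genes named in the text were chosen by a rule fixed before the data were examined: the 6 largest rises and the 6 largest falls among genes past the threshold with a mean log2 CPM of at least 5 and no overlap between the groups, the 2 members of each list with the smallest p, and 10 genes of quorum sensing and iron uptake in every case (lasI, lasR, rhlI, rhlR, pqsA, mvfR, lasB, rhlA, phzM and pvdS). This gave 56 genes. All other genes named in the text were chosen after their values were seen, and so were the parts into which some lists were divided.

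The fit was tested on simulated data for this comparison, with counts drawn for the same 6 libraries and 200 of 5242 genes changed. It recovered 52.6% of the genes changed 2-fold and 97.0% of those changed 4-fold, and 4.50% of its 154 calls were false. A simulated list shifted by 1 log2 unit was called and no unshifted list was called. Simulated genes were drawn independently of each other, whereas in the data the estimated correlation of the shifted list, heat shock and chaperones, was 0.87. In the data 63.7% of genes changed. The simulation therefore does not test the preset correlation for lists like these. Alternatives covered DESeq2 1.42.0, limma-voom, RLE, upper-quartile and total-count scaling, no low-count filter, a filter of 10 CPM in 3 libraries, the replicate number as a block, a non-robust fit, a 2-fold minimum and leaving out each library in turn. After the data were seen, limma on log2(FPKM + 1), list counts without DATS replicate 2 and the phenazine list with copies of identical counts counted once were added. Random lists of equal size, matched on mean expression or on length, were drawn 10000 times. Tables and figures were made with Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.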

Results

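Gene expression was measured by RNA sequencing in 3 control and 3 DATS-treated samples of P. aeruginosa PAO1, taken after 5 h. The libraries held 4073536 to 6912818 counted reads, and 5280 genes were tested. The single comparison implied by the design asks which genes differ between treated and untreated cultures.

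In DATS samples, genes for many secreted virulence factors were nearly silent, while ribosomal protein and chaperone genes had median log2 fold changes of 2.91 and 2.17 over control and 11 of 15 drug efflux pump genes rose. By edgeR's quasi-likelihood test, 3361 genes changed, of which 1702 were higher and 1659 lower in DATS, and 1101 and 1161 of these differed at least 2-fold. Among the 6 named falls the largest was in aprA, the alkaline protease, from 10260 ± 720 to 10.2 ± 2.67 CPM (SD, n = 3; log2 fold change −9.96, SE 0.29). The gene rhlA, for an enzyme of rhamnolipid surfactant synthesis, went from 1216 ± 37.2 to 4.70 ± 0.813 CPM (log2 fold change −8.02). The lectin gene lecB, the elastase gene lasB and the chemotaxis methyltransferase gene PA0175 followed, with log2 fold changes of −7.90, −7.77 and −7.69. PA1168, which encodes an uncharacterised protein, had 1241 counts over the control libraries and 2 over the DATS libraries, a ratio of 709 (95% exact binomial interval 196 to 5860). Among the 6 named rises the largest was in PA1240, an enoyl-CoA hydratase by its annotation, from 3.80 ± 0.355 to 1121 ± 269 CPM (log2 fold change 8.20, SE 0.28). It was followed by fhp, the flavohemoprotein that detoxifies nitric oxide, at 7.50, by PA4623 at 7.46, PA2048 at 6.90, PA4881 at 6.71 and PA0492 at 6.46. The largest adjusted p among these 12 genes was 0.0014, for PA4881. Of the 20 gene lists, camera with the preset correlation called 15, 5 higher and 10 lower. It also called 9 to 16 lists in splits that mixed control and DATS libraries, which keep part of the difference between the groups. With an estimated correlation it called only the quorum-controlled exoproducts. Without scaling factors, by total count alone, the median log2 fold change of all genes tested was −0.20 in place of 0.01, and no list median changed sign.

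**Figure D1:**
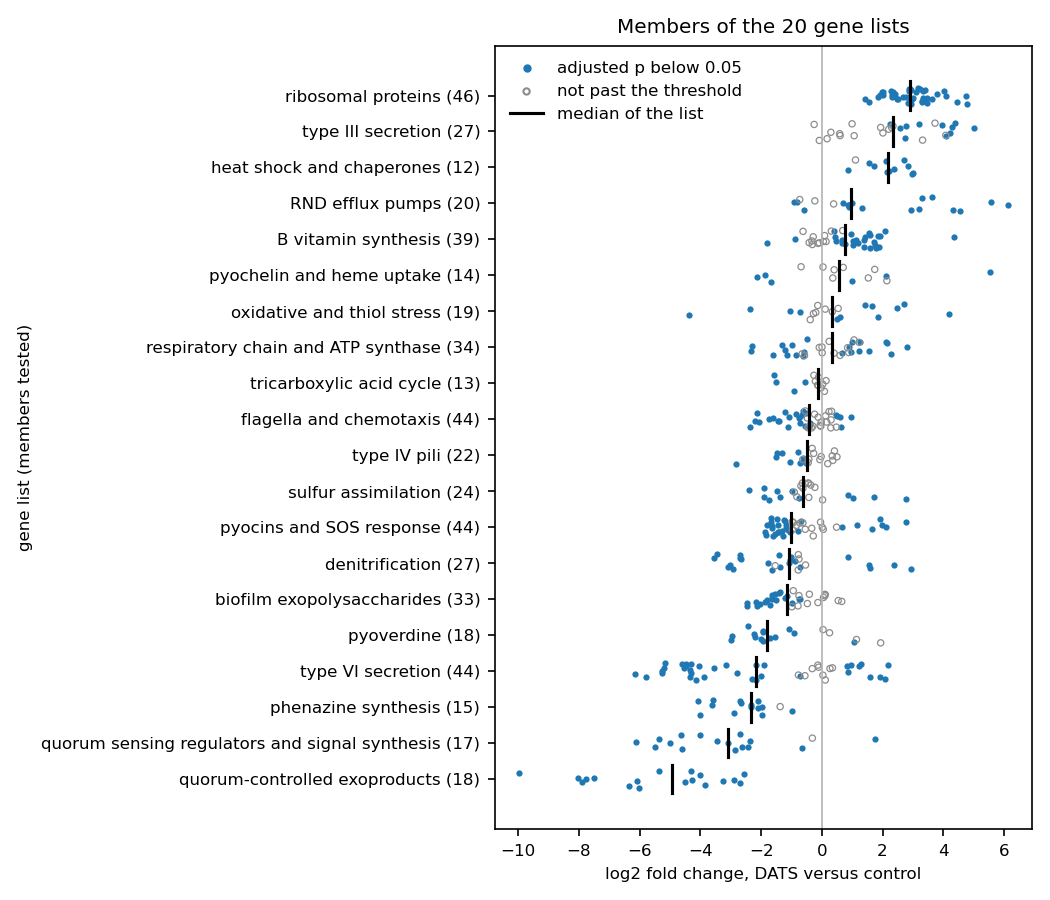
Log2 fold change between DATS and control (horizontal axis) of each tested member of the 20 gene lists (vertical axis, with the number tested). Filled points passed the threshold of edgeR's quasi-likelihood test, open points did not, and black bars are list medians, which run from −4.93 for the quorum-controlled exoproducts to 2.91 for the ribosomal proteins.

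Quorum sensing, the cell-density signalling that controls many secreted products of this species, was strongly altered. Of the 17 regulators and signal synthesis genes, 15 fell, 1 rose and qscR did not pass the test, with the same numbers adjusted over the list alone. The gene that rose was lasI, which makes the long-chain acyl-homoserine lactone signal, from 439 ± 50.7 to 1495 ± 289 CPM (SD, n = 3; log2 fold change 1.77, adjusted p = 3.21e-05). Its receptor gene lasR fell by 0.65 on the log2 scale (adjusted p = 0.00614). The genes of the rhl system, which makes and senses the short-chain signal, fell, with log2 fold changes of −4.99 for rhlI and −2.43 for rhlR. So did the quinolone signal genes, with pqsA going from 323 ± 36.7 to 20.2 ± 3.10 CPM (SD, n = 3), pqsE at −4.61 and their activator gene mvfR at −2.71. All 18 quorum-controlled exoproduct genes fell, 18 also when adjusted over the list alone, with a median log2 fold change of −4.93. They include the elastase genes lasB and lasA, the rhamnolipid genes rhlA and rhlB, the lectin genes lecA and lecB and the chitinase gene chiC. Camera called the regulators lower (adjusted p = 1.47e-06) but not with an estimated correlation (adjusted p = 0.0898 with an estimated correlation). It called the exoproducts lower with both, at adjusted p = 1.05e-10 with the preset and adjusted p = 0.0382 with an estimated correlation, the latter moving to 0.106 without DATS replicate 2.

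**Figure D2:**
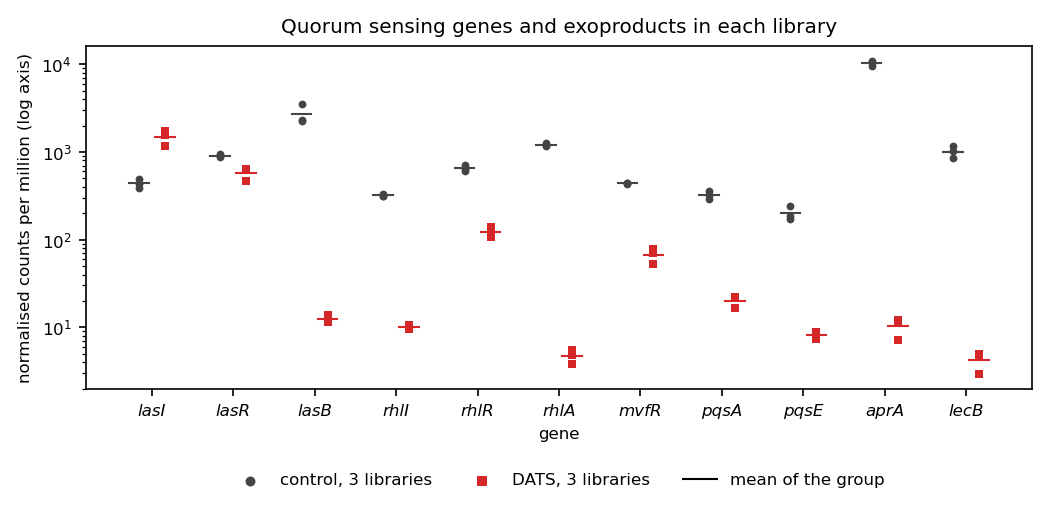
Normalised counts (CPM, log axis) of 11 quorum sensing and quorum-controlled genes in each of the 3 control libraries (circles) and 3 DATS libraries (squares), with bars at the group means. The DATS libraries lie above the control libraries for lasI, at 1495 against 439 CPM on average, and below them for the other genes shown.

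Phenazines, the redox-active pigments whose synthesis is also under quorum control, had mostly lower transcript levels as well. Of the 15 phenazine genes tested, 14 fell and phzC1 did not pass the test, with the same numbers adjusted over the list alone. The methyltransferase gene phzM fell from 49.0 ± 1.16 to 7.70 ± 0.464 CPM (SD, n = 3; log2 fold change −2.67), and phzB1 fell by 4.03 on the log2 scale. Values of phzA1, phzC1 to phzG1 and phzC2 to phzF2 are uncertain because their near-identical copies share reads. The copies of phzD, phzE and phzF had identical counts, so the 14 falls rest on 11 sets of values, and with such copies counted once the list was called at adjusted p = 3.74e-05, and at adjusted p = 0.295 with an estimated correlation. The list was called lower (adjusted p = 4.25e-06), but not with an estimated correlation (adjusted p = 0.295 with an estimated correlation). Gene by gene, its members lay a median of 0.40 higher in DATS replicate 2 than in the mean of the other DATS libraries.

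Ribosomal protein genes rose without exception among the 46 tested, 46 also when adjusted over the list alone, with a median log2 fold change of 2.91 and a range of 1.44 to 4.77. The gene of the small-subunit protein S8, rpsH, went from 122 ± 10.5 to 1961 ± 63.5 CPM (SD, n = 3; log2 fold change 4.01), and that of the large-subunit protein L6, rplF, from 314 ± 29.0 to 4312 ± 223 CPM (3.78). Camera called the list higher (adjusted p = 2.86e-20), but not with an estimated correlation (adjusted p = 0.151 with an estimated correlation). Of the 12 heat shock and chaperone genes, 11 rose and clpB did not pass the test, with the same numbers adjusted over the list alone. The folding chaperone pair groEL and groES rose by 2.85 and 2.36, groEL from 2173 ± 153 to 15620 ± 3467 CPM. The list was called higher (adjusted p = 0.000574), but not with an estimated correlation (adjusted p = 0.532 with an estimated correlation). Its median relative to control was 2.98 in DATS replicate 2, against 1.36 and 1.79 in DATS replicates 1 and 3, and without DATS replicate 2 the list still had 11 risen members.

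The list of multidrug efflux pumps of the resistance-nodulation-division family held 15 pump genes, of which 11 rose. Its 5 other members were the regulator genes mexR, nfxB, mexT and mexZ and the oxidoreductase gene mexS, and 3 of these 5 rose. Of all 20 members tested, 14 rose, 3 fell (mexG, mexH and mexI) and 3 did not pass the test, and 14 rose and 4 fell when adjusted over the list alone. The members mexX and mexY (PA2019 and PA2018), of a pump that exports aminoglycosides, had the log2 fold changes 6.12 and 4.56, and their repressor gene mexZ (PA2020) rose by 2.93. The pump genes mexE, mexF and oprN rose by 5.59, 3.64 and 3.19, with mexF at 56.8 ± 7.39 CPM in control and 708 ± 217 CPM in DATS (SD, n = 3), while their activator gene mexT was at −0.23 and did not pass the test (adjusted p = 0.193). The pump genes mexA, mexB and oprM rose by 1.32, 0.90 and 0.71. Camera called the list higher (adjusted p = 0.00349), but not with an estimated correlation (adjusted p = 0.295 with an estimated correlation).

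Genes for oxidative and thiol stress, sulfur assimilation and B vitamins were examined because diallyl sulfide, named in the protocol, is an organosulfur compound. Among the 19 oxidative and thiol stress genes 8 rose and 4 fell (katA, sodB, ahpC and gshA), with the same numbers adjusted over the list alone, and the list was not called (adjusted p = 0.387). The main catalase gene katA fell from 7011 ± 582 to 340 ± 67.9 CPM (SD, n = 3; log2 fold change −4.36) and the superoxide dismutase gene sodB fell by 2.35. The other superoxide dismutase gene, sodM, rose by 4.20 (adjusted p = 0.0305), with 582, 24.4 and 385 CPM in DATS replicates 1, 2 and 3 and 18.0 ± 2.80 CPM in control (SD, n = 3), and the redox sensor gene soxR rose by 2.48, the organic peroxide regulator gene ospR by 2.71 and the glutathione reductase gene gor by 1.84. Among the 24 sulfur assimilation genes 4 rose (cysE, cysK, cysM and PA3442) and 8 fell, with the same numbers adjusted over the list alone, and the list was not called (adjusted p = 0.0593). The sulfate-binding protein gene sbp fell by 2.40 and the sulfate transporter gene cysA by 1.74, while cysE, the first enzyme of cysteine synthesis from serine, rose by 2.78. Of the 39 B vitamin genes 25 rose and 2 fell (pdxA and bioD), with the same numbers adjusted over the list alone. The thiamine gene thiI, which also acts in tRNA thiolation, rose by 4.37 and the cobalamin gene cobN by 1.92. This list was called higher (adjusted p = 0.000861), but not with an estimated correlation (adjusted p = 0.0911 with an estimated correlation). Without control replicate 2, 5 oxidative and thiol stress genes rose. Sulfur assimilation genes lay a median of 0.30 higher, gene by gene, in DATS replicate 2 than in the other DATS libraries. Without DATS replicate 2, 12 of the 24 sulfur genes fell and camera called that list lower (adjusted p = 0.0279). Camera also called it lower without DATS replicate 3 (adjusted p = 0.0458) and with the replicate number as a block (adjusted p = 0.048), as did fry (adjusted p = 0.00713). With all libraries the sulfur list had adjusted p = 0.532 with an estimated correlation, and without DATS replicate 2 adjusted p = 0.365 with an estimated correlation. Fry also called the oxidative and thiol stress list higher (adjusted p = 0.0252).

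Type VI secretion genes, which encode needle-like machines that inject effectors into neighbouring cells, fell in 26 of 44 cases and rose in 9, with the same numbers adjusted over the list alone. When the list was divided into its 3 gene clusters after its values were seen, all 13 tested genes of the cluster called H2 and 12 of 13 of H3 fell, with medians of −4.47 and −2.80, while 9 of 18 genes of H1 rose and 1 fell, with a median of 0.60. The Hcp family gene PA2367 of H3 fell from 102 ± 11.1 to 1.43 ± 0.130 CPM (SD, n = 3; log2 fold change −6.15) and PA1665 of H2 fell by 5.20. The list was called lower (adjusted p = 0.000342), but not with an estimated correlation (adjusted p = 0.372 with an estimated correlation). Gene by gene, its members lay a median of 0.24 higher in DATS replicate 2 than in the mean of the other DATS libraries.

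Genes for motility and for the biofilm matrix fell more often than they rose. Of 44 flagellar and chemotaxis genes 21 fell and 5 rose (fleQ, flgF, fliG, fliM and fleN), with the same numbers adjusted over the list alone. The largest falls in this list were in genes of the filament and its cap and junction, with fliD at −2.37, flgK at −2.19 and the flagellin gene fliC at −2.14, and fliC dropped from 23030 to 5231 CPM on average. The master regulator gene fleQ rose by 0.97. Of 22 type IV pilus genes 10 fell and none rose by edgeR's test, DESeq2 or limma-voom, with the same numbers adjusted over the list alone and 0 higher at an unadjusted p under 0.05, led by the minor pilin gene pilE at −2.83 and the tip adhesin gene pilY1 at −1.51. Of 33 exopolysaccharide genes 20 fell and none rose by edgeR's test, with the same numbers adjusted over the list alone, with 0 of them higher by DESeq2 or limma-voom and 1 at an unadjusted p under 0.05. When this list was divided after its values were seen, 13 of 14 psl genes fell, among them pslL at −2.46, and none of 6 pel genes passed by edgeR's test, DESeq2 or limma-voom, with 1 higher at an unadjusted p under 0.05. Of the genes for the matrix adhesin CdrA and its transporter, PA4624 (cdrB) fell by 2.45. These lists were called lower at adjusted p = 0.0196 for flagella, 0.0335 for pili and 0.000146 for exopolysaccharides. None was called with an estimated correlation, with adjusted p = 0.295, adjusted p = 0.532 and adjusted p = 0.295 with an estimated correlation. Without DATS replicate 1 the pilus list was not called (adjusted p = 0.0932) and 2 of its genes rose. Pilus genes lay a median of 0.25 higher, gene by gene, in DATS replicate 2 than in the other DATS libraries. Without DATS replicate 2, 14 pilus genes fell and 1 rose. Without DATS replicate 1, 1 of the 33 exopolysaccharide genes rose, a pel gene, and without DATS replicate 2, 2 of the 6 pel genes fell. Without control replicate 2 there were 3 risen flagellar genes.

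Of 18 pyoverdine genes, which make and import the main siderophore, 13 fell and 1 (fpvI) rose, with the same numbers adjusted over the list alone. The peptide synthetase gene pvdL fell from 245 ± 68.4 to 30.6 ± 8.30 CPM (SD, n = 3; log2 fold change −2.99) and pvdO fell by 2.96. The sigma factor gene pvdS did not pass the test (log2 fold change 1.94, SE 0.86, adjusted p = 0.107). With all libraries it passed by DESeq2 (adjusted p = 0.0421) and by the non-robust edgeR fit (adjusted p = 0.0344), but not by limma-voom. Its levels were 133, 13.7 and 113 CPM in DATS replicates 1, 2 and 3 and 22.6 ± 5.58 CPM in control, and without DATS replicate 2 it passed (log2 fold change 2.45, adjusted p = 2.76e-08). Of 14 genes for pyochelin, the secondary siderophore, and for heme uptake, 3 rose (pchR, phuR and hasR) and 3 fell (pchG, PA4223 and pchF) over all genes, and 1 rose and 3 fell when adjusted over the list alone. The pyochelin regulator gene pchR was at 533, 38.3 and 456 CPM in DATS replicates 1, 2 and 3 and 7.36 CPM on average in control, while pchG and its neighbour PA4223, known as pchH, fell by 2.14 and 1.86. The list's median relative to control was 1.23, −1.37 and 0.71 in DATS replicates 1, 2 and 3. Pyoverdine was called lower (adjusted p = 0.00496), but not with an estimated correlation (adjusted p = 0.501 with an estimated correlation). The pyochelin and heme list was not called (adjusted p = 0.84), and its median of 0.56 and mean of 0.66 had the opposite sign to camera's direction. Without DATS replicate 2, 5 pyoverdine and 8 pyochelin and heme genes rose, and without any other single library 1 pyochelin and heme gene rose. By limma-voom 0 pyochelin and heme genes rose, and by DESeq2 4.

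Type III secretion genes, which inject toxins into host cells, differed most in DATS replicate 2. Of 27 tested, 11 rose and none fell over all genes, but none passed when adjusted over the list alone, by edgeR's test. At an unadjusted p under 0.05, 17 were higher and none lower, and of these 27 genes DESeq2 called 19 higher and limma-voom 2. The toxin gene exoT rose from 34.0 ± 3.22 to 578 ± 595 CPM (SD, n = 3; log2 fold change 4.09, adjusted p = 0.0123) and the needle tip gene pcrV from 13.3 ± 1.60 to 277 ± 314 CPM (log2 fold change 4.38, adjusted p = 0.0161). The list's median relative to control was 0.93, 3.49 and 1.61 in DATS replicates 1, 2 and 3. Camera called it higher (adjusted p = 0.00315), but not with an estimated correlation (adjusted p = 0.646 with an estimated correlation), and fry did not call it (adjusted p = 0.12). Without DATS replicate 2, exoT and pcrV rose by 2.79 and 2.85 and 18 of the 27 genes rose and 1 fell, and without DATS replicate 1, 20 of them rose. Without control replicate 1, 2 or 3, 2, 1 and 2 of them rose and pcrV did not pass the test (adjusted p = 0.0557, 0.0524 and 0.0532).

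**Figure D3:**
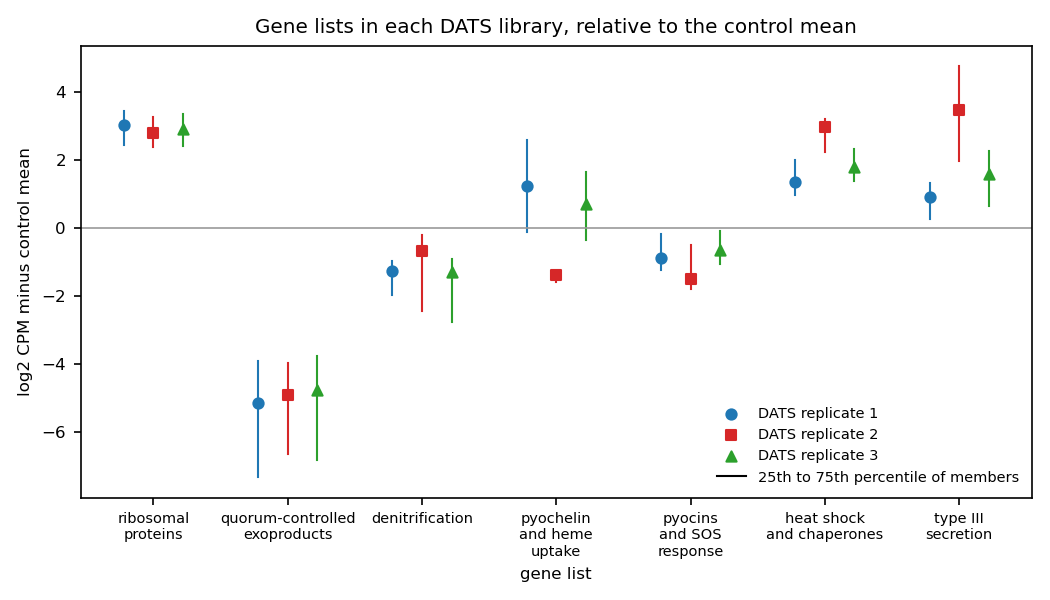
Median log2 CPM of 7 gene lists (horizontal axis) in each DATS library, minus the mean of the 3 control libraries (vertical axis), with lines from the 25th to the 75th percentile of the members. The 3 DATS libraries lie close together for ribosomal proteins, at 3.03, 2.79 and 2.92, while DATS replicate 2 stands apart for pyochelin and heme uptake, at −1.37 against 1.23 and 0.71, and for type III secretion, at 3.49 against 0.93 and 1.61.

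Denitrification genes, which respire nitrate to nitrogen gas, changed in both directions. Of 27 tested, 17 fell and 5 rose (norB, norC, PA0525, nosR and nirQ) over all genes, and 19 fell and 5 rose when adjusted over the list alone. The nitric oxide reductase genes norC and norB rose by 2.38 and 1.59, with norC at 2541 ± 334 CPM in control and 13200 ± 1528 CPM in DATS (SD, n = 3), and the activator gene nirQ rose by 2.93. The nitrate reductase gene narG fell by 3.44 and the nitrite reductase accessory gene nirN by 3.56, while the nitrite reductase gene nirS itself was at −0.75 and did not pass the test (adjusted p = 0.0529). The list was called lower (adjusted p = 0.0222), but not with an estimated correlation (adjusted p = 0.646 with an estimated correlation) or by fry (adjusted p = 0.0848). Its median relative to control was −1.27, −0.66 and −1.30 in DATS replicates 1, 2 and 3, and without DATS replicate 2 there were 19 genes that fell and 5 that rose.

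Genes of energy metabolism moved in both directions. Among 13 tricarboxylic acid cycle genes 4 fell and none rose by edgeR's test, DESeq2 or limma-voom, with the same numbers adjusted over the list alone and 0 higher at an unadjusted p under 0.05, namely the citrate synthase gene gltA at −1.56, the aconitase gene acnA at −1.50, acnB and sucA, and the list was not called by camera (adjusted p = 0.198) but was called lower by fry (adjusted p = 0.0268). Among 34 respiratory chain and ATP synthase genes 11 rose and 11 fell, with the same numbers adjusted over the list alone, and the list was not called (adjusted p = 0.816). When it was divided after its values were seen, 7 of 9 ATP synthase genes rose, with atpF at 2.29 and atpE at 2.11, and 9 of 13 genes of NADH dehydrogenase I fell while nuoB rose. Leaving out any control replicate lowered the risen respiratory genes to 7, as did limma-voom.

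Bacteriocin genes mostly fell and DNA damage genes rose. Of 44 tested, 24 fell and 7 rose over all genes, and 25 fell and 7 rose when adjusted over the list alone. The pyocin genes pyoS5 and PA3866 fell by 1.88 and 1.84, although PA3866 shares reads with a copy and is uncertain. When the list was divided after its values were seen, 21 of 35 genes of the R and F pyocin cluster fell and 2 (prtN and ptrB) rose. The DNA damage genes recA, lexA, recN, sulA (PA3008) and recX (PA3616) rose, lexA by 2.76 and recA by 1.92. The list was called lower (adjusted p = 0.0381), but not with an estimated correlation (adjusted p = 0.714 with an estimated correlation). Its median was −1.49 in DATS replicate 2, against −0.89 and −0.64 in DATS replicates 1 and 3, and the call was lost without DATS replicate 2 (adjusted p = 0.135), DATS replicate 1 (0.0528), control replicate 2 (0.0989) or control replicate 3 (0.072), by total-count scaling (0.079), with the filter of 10 CPM in 3 libraries (0.0645), with limma on log2(FPKM + 1) (0.0787) and by fry (0.196).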

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

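The FPKM fit, the counts of list members without DATS replicate 2 and the phenazine list with identical copies counted once were chosen only after the data were seen. The count of 3361 changed genes moved to between 3274 and 3397 under the DESeq2, limma-voom, scaling, block, non-robust and unfiltered alternatives and to 3027 with the 10 CPM filter, which tests fewer genes; no gene called in the main test and under any alternative changed sign. Leaving out each library gave 2928 to 3608 changed genes, 1449 to 1807 higher and 1479 to 1801 lower, with 13 to 16 lists called. Asking for at least 2-fold left 1101 higher genes. Camera with an estimated correlation called 1 list in place of 15. For exoproducts and B vitamins the estimated correlation was 0.00178 and −0.00352, below the preset 0.01. Their adjusted p still rose, to 0.0382 and 0.0911, so a higher correlation does not account for the change in these lists. A call lost with an estimated correlation is therefore not by itself evidence that a list did not change. The cause of the rise in adjusted p was not tested further. Fry also called 15, but not denitrification (adjusted p = 0.0848), type III secretion (0.12) or pyocins (0.196), and in their place oxidative and thiol stress (0.0252), sulfur assimilation (0.00713) and the tricarboxylic acid cycle (0.0268). Total-count scaling shifted fold changes by −0.21 and gave 1408 higher and 1979 lower genes, and limma on log2(FPKM + 1) gave 1385 and 2002. Camera's direction for pyochelin and heme uptake reversed under total-count scaling (median 0.336), the 10 CPM filter (1.08), leaving out DATS replicate 2 (1.01) and the FPKM fit (−0.0184), in no case past the threshold, with adjusted p from 0.112 to 0.96. Leaving out each library in turn gave it medians from −0.03 to 1.01. The cause was not tested. Of 838 values of the 56 named genes, 832 kept their direction and side of the threshold, 3, all of pcrV, lost the call and 3, all of pvdS, gained it. With the replicate number as a block, 3274 genes changed, 1642 higher and 1632 lower, and 16 lists were called, with sulfur assimilation added (adjusted p = 0.048). The deviations of same-numbered libraries correlated at 0.072, 0.053 and −0.022, against −0.068 to 0.026 for differently numbered libraries. With so few libraries these values do not settle whether the numbers pair the samples. The pseudocount and no-filter alternatives planned for a table without counts were not run, because counts were given. Depth limits genes near the floor of 0.434 to 0.736 CPM.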

Other observations

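The tests of mixed RNA and of oxygen or iron in DATS replicate 2, the comparison of its label test with the control libraries, the tests of annotated pathways, and the groups of MexT-linked and arginine deiminase genes were chosen only after the results were seen.

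The 16 genes listed here as linked to the efflux regulator MexT were drawn up after their values were seen and rose, with a median log2 fold change of 3.47, so their number is no test of that regulator. They include PA4623 and PA4881 of the 6 named rises, mexE, mexF, oprN and the oxidoreductase gene mexS (PA2491, at 3.31) of the fixed efflux list, PA3229 at 5.90, PA1970 at 5.78 and xenB at 2.06. In DATS replicate 2 their median relative to control was 2.59 against 3.60 and 3.68 in the other DATS libraries. PA5471, whose product relieves repression of the mexXY pump genes, went from 14.6 ± 1.66 to 717 ± 32.1 CPM (SD, n = 3; log2 fold change 5.62, adjusted p = 4.58e-08 by edgeR's quasi-likelihood test), and its neighbour PA5470 rose by 5.73. In the arginine deiminase operon, which makes ATP from arginine without oxygen, arcA, arcB and arcC fell by 4.09, 4.95 and 4.90, arcB from 14350 ± 84.1 to 464 ± 95.2 CPM. The transporter gene arcD of the same operon was at 556, 9199 and 534 CPM in DATS replicates 1, 2 and 3 and 7030 ± 805 CPM in control (SD, n = 3) and did not pass the test (log2 fold change −1.04, adjusted p = 0.514). The oxygen-sensing regulator gene anr fell by 2.33, and the periplasmic nitrate reductase gene napA fell by 6.55.

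Among the 75 pathways of the deposited annotation with at least 10 tested genes, camera called 12 with the preset correlation and none with an estimated correlation, where the lowest adjusted p was 0.533. Genes that charge transfer RNAs with amino acids rose in 25 of 28 cases and fell in 1 (adjusted p = 3.14e-05), porphyrin genes rose in 28 of 45 and fell in 6 (adjusted p = 0.00845), and protein export genes rose in 13 of 17 and fell in 1 (adjusted p = 0.00951). Chemotaxis genes fell in 32 of 46 cases and rose in 4 (adjusted p = 4.01e-05), and starch and sucrose genes fell in 11 of 18 and rose in 2 (adjusted p = 0.0391).

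Ribosomal proteins were higher and quorum-controlled exoproducts lower in DATS. The choice among 5 scalings did not change this, since the ribosomal median was at least 2.70 and the exoproduct median at most −4.89. These scalings shifted fold changes by only −0.209 to 0.0416 from TMM, too little to undo either change. A scaling error common to all 5 was therefore not tested. Gene length is argued against, since the ribosomal median lay 2.36 above the central 95% of length-matched random lists (−0.40 to 0.55). A difference in growth stage may contribute and cannot be told apart from treatment here: of 11 stationary phase genes 10 fell, among them rpoS at −3.21, and only psrA rose, by 2.60, with a median of −2.83, below expression-matched random lists (−1.02 to 1.20), while of 13 growth machinery genes 11 rose and only ftsZ fell, with a median of 1.41 near the upper end of such lists (−0.93 to 1.54, 95.48th percentile). Several growth machinery genes, such as rpoB, rpoA, fusA1, tufA and tsf, lie beside ribosomal protein genes by locus tag. Their rise is therefore not independent of the ribosomal result. What keeps growth stage open is that all cultures were taken at 5 h, so stage and treatment would differ together. The labels give exponential growth phase for all 6 samples without a growth measurement. A direct response to the treatment stays open as well, untested.

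DATS replicate 2 stood apart from the other DATS libraries, with a correlation of log2 CPM of 0.949 and 0.960 to them against 0.986 between them, and 140 genes at least 4-fold away. Control RNA mixed into it could not account for this: 19 genes raised in it would need a median of 88.3% control RNA, whereas 67 genes nearly silent in DATS replicates 1 and 3 stood at a median of 1.79% of the control level, against 1.58% in those libraries. A control library under a DATS label missed the bound of 90% set in advance for arguing against it, since 89.6% of 972 genes that differ at least 4-fold lay nearer to the other DATS libraries, but a comparison added after that value was seen argues against it, as each control library had at most 0.529% of such genes nearer to DATS. Less oxygen or more iron in that culture stays open. As medians of gene-by-gene differences, its denitrification genes lay 0.36 above the other DATS libraries and its pyochelin and heme genes at −2.37 relative to them. Both deviations had been seen before this hypothesis was written, and 10 of the 20 lists lay outside the range of expression-matched random lists, so they do not single it out. Within denitrification, members differed in both directions. Relative to control, narK1 was at −0.214 in DATS replicate 2 against −3.52 and −3.44 in DATS replicates 1 and 3. For nosR the values were 2.25 against 0.825 and 1.19. But narG, narH, narI and narJ were lower in DATS replicate 2, with narG at −3.99 relative to control against −2.74 and −3.30. By the same measure, the type III secretion, heat shock, pyocin, pyoverdine and phenazine lists lay at 2.33, 1.21, −0.69, −0.61 and 0.40 relative to the other DATS libraries, which the hypothesis was not written to cover.

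The 6 libraries make only 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 3361 changed genes, 1702 higher and 1659 lower, and was the 1 split with as many, since the highest other count by edgeR's test was 0, with at most 100 genes at an unadjusted p under 0.05. A count near 0 was likely in advance in the mixed splits, since the DATS difference then lies within the groups and widens their spread. The contrast of 3361 with 0 therefore does not measure what chance would give. For gene lists, 2 of the 10 splits gave as many calls with the preset correlation, the real one with 15 and the split of control replicates 1 and 2 with DATS replicate 3 against the rest with 16. Splits that mixed the groups called 9 to 16 of the 20 lists, although each had 0 changed genes. The number of lists called is therefore not particular to the real split. However, each mixed split sets 2 libraries of 1 group beside 1 of the other, so part of the DATS difference remains in it. These splits therefore cannot show how many lists would be called without a difference between the groups.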
